A study of Caulobacter vibrioides with 24 samples.

How the data were processed

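The series profiled mRNA decay by total RNA sequencing in wild-type Caulobacter crescentus NA1000. Cultures received chloramphenicol or retapamulin, and transcription was then stopped with rifampicin at 100 ug/mL. Samples were taken just before rifampicin (time 0) and at 1, 2, 4, 8 and 15 minutes. The labels give 24 samples in 12 groups of drug by time, with 2 replicates in each group. Per the labels' protocols, rRNA was depleted and tRNA was left in as a stable internal control. The labels name no culture without a ribosome inhibitor.

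The deposited table gives RPKM, a read number scaled to gene length and to the mapped reads of the library, computed by the authors. Reads were aligned with Bowtie 0.12.8, per the submitters' processing notes. The genome build, annotation and counting program are not stated. The table holds 3936 genes, of which 3885 are coding and 51 are tRNA. All 3885 coding identifiers matched the locus tags of the ASM2200v1 reference, which gave a symbol to 665. That reference holds no product names, so TonB-dependent receptors were not analysed here. Ribosomal RNA, tmRNA, rpoB, groEL and rpsA were not analysed here either.

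The 24 columns do not hold 24 libraries. The columns of chloramphenicol at 0 and 2 minutes are identical within each replicate, so they are 1 library per replicate whose time is either 0 or 2 minutes. The columns of retapamulin at 2 minutes in replicate 1 and at 0 minutes in replicate 2 are blank. This leaves 20 distinct libraries, 10 per drug. Within a library, RPKM times gene length (less 31 bases) is a whole multiple of 1 step, which gave the read numbers and the read total of each library. At least 99.9% of values per library came out whole within 0.05 reads. The smallest listed value is 26 reads, so a blank stands for at most 25 reads and was treated as missing, not as 0. At 26 reads the counting error is 19.6% of the value. Intervals and errors of this kind cover counting only.

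Tests used limma 3.58.1 in R 4.3.3 on log2(RPKM + 1). Fold changes are on that scale, which understates the change of low genes. Genes with a mean of listed values of at least 10 RPKM were tested. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. For the comparison at time 0, values were used as deposited and all 20 libraries in the 11 groups with values shared 1 estimate of the spread, with 9 residual degrees of freedom. Retapamulin has 1 library at time 0, so it was assumed to vary like the other groups. Chloramphenicol is represented by the repeated library of each replicate, under its 0-minute label.

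For decay, each library was scaled to tRNA by the median of the 10 tRNA genes listed in every library. A least-squares slope against minutes was fitted for each of the 4 series of drug and replicate, over genes listed at 3 or more times in a series. The repeated library was left out, so a chloramphenicol series has 4 times and a retapamulin series 5. The slopes, 2 per drug, were compared with limma. The half-life is -1 divided by the slope, given where the slope is negative. A relative comparison first subtracted the median slope of each series. Gene lists with at least 3 tested members were tested with camera (preset correlation 0.01), and again with an estimated correlation. Of 33 lists fixed in advance, 26 could be tested at time 0 and on centred chloramphenicol slopes, and 18 on retapamulin slopes and on the slope difference. The design had assumed that camera gives the same result with slopes centred or not. It does not, so the result on slopes as fitted is the one reported and the centred result stands beside it.

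The named genes follow a rule fixed before the data were examined. It takes up to 10 genes with a symbol in each direction with the largest change past the threshold and no overlap between the drugs' libraries, and 1 gene without a symbol. It also takes the 5 shortest and 5 longest half-lives at a fitted level of at least 50 RPKM, up to 4 members per list, and a fixed set that includes ctrA, dnaA, ftsZ, rsaA, rne, dnaK, recA, pilA and fljK. Where nothing passed, the 5 smallest p-values in each direction were taken, here among genes with a symbol. The lists, the tests and most alternatives were also fixed before the data were examined. The handling of the repeated and blank columns, the treatment of blanks, the minimum of 3 times and the alternatives built on them were chosen after the data were seen.

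The steps were tested on simulated reads drawn from the real gene levels and read totals with a dispersion of 0.05 and 200 changed genes. At time 0, 17 of 93 tested genes with a log2 change of 1 were recovered, and 75 of 78 with a log2 change of 2, with 8 calls among 2689 unchanged genes (2860 genes tested). For the relative slope difference, 3 of 40 tested genes with a change of 0.1 log2 per minute were recovered, and 35 of 50 with a change of 0.2, with 8 calls among 864 unchanged genes (954 genes tested). The simulation held tRNA constant, gave every gene the same dispersion and had no shift between series and no length trend. The real data may therefore hold more false calls than these counts. Alternatives covered the pseudocount (0.1 and 10), the filter (none and 50 RPKM), scaling, the window of times, a single fit of all libraries, the replicate number as a term, each replicate left out, the placing of the repeated library, and a Tobit fit (survival 3.8-3) with blanks as values of at most 25 reads. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the values and drew the plots.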

Results

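Caulobacter crescentus is a freshwater bacterium whose motile swarmer cells become stalked, dividing cells. Its mRNA was followed after rifampicin, which stops new transcription, in cells held in chloramphenicol, an inhibitor that arrests elongating ribosomes, or retapamulin, which traps ribosomes at initiation. The 20 distinct libraries hold between 169968 and 5828702 mapped reads. Chloramphenicol libraries range from 2449026 to 5828702 reads and retapamulin libraries from 169968 to 2627842. The shallowest library, retapamulin at 1 minute in replicate 2, lists 686 of 3885 coding genes, and 227 coding genes are listed in all 20 libraries.

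In retapamulin, reads in listed coding genes shrank from 57.4% of the library at time 0 to 9.60% at 15 minutes in replicate 1 (at most 16.2% if every blank gene had 25 reads). In replicate 2 they shrank from 41.3% at 1 minute, where blanks allow up to 88.3%, to 7.42% at 15 minutes, where they allow up to 16.9%. In chloramphenicol the share stayed between 55.5% and 61.4% at every time in both replicates. The tRNA internal control was not flat. Its level as deposited changed by -0.096 and -0.023 log2 per minute in the chloramphenicol replicates and by -0.067 and -0.063 in the retapamulin replicates.

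**Figure D1:**
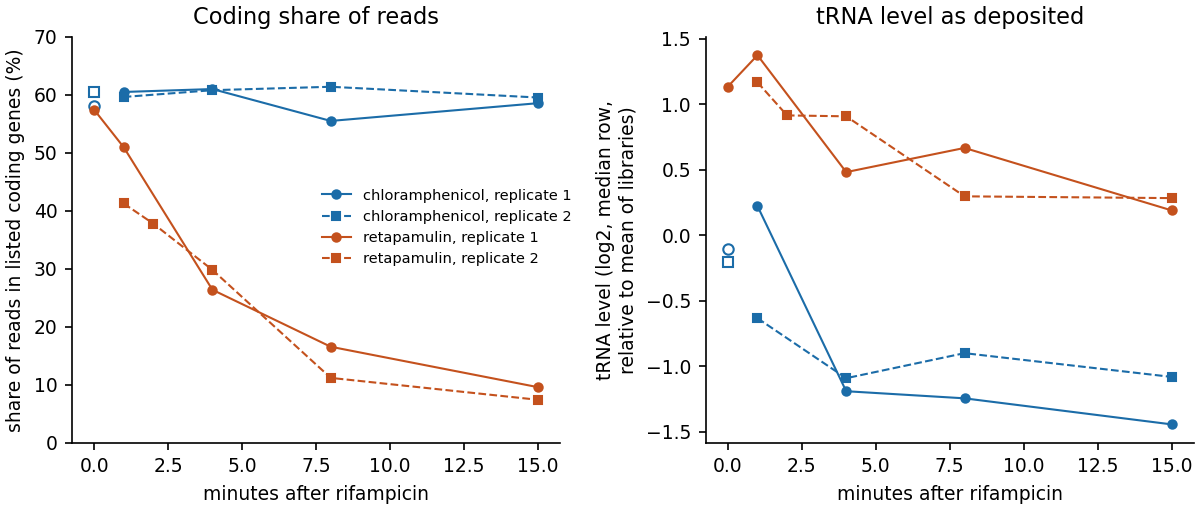
Left, share of reads in listed coding genes (percent) against minutes after rifampicin for each replicate; right, the median tRNA level (log2, relative to the mean of all libraries) against the same times. Open symbols are the chloramphenicol library deposited under both 0 and 2 minutes, drawn at 0. The coding share ends at 9.60% and 7.42% in retapamulin and at 58.5% and 59.5% in chloramphenicol.

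The first comparison sets the drugs side by side under their 0-minute labels, although the chloramphenicol library may have been taken at 2 minutes. For gene levels at time 0, fell and rose mean lower and higher in retapamulin than in chloramphenicol. Without a culture free of ribosome inhibitors, which drug changed a gene cannot be told. The genes of a terminal quinol oxidase of the respiratory chain were far lower in retapamulin. qoxB had 70.8 RPKM in retapamulin against 1380 ± 2.60 (SD, n = 2) in chloramphenicol, a log2 change of -4.26 ± 0.16 (SE, adjusted p = 4.49e-08). qoxA, qoxC and qoxD fell with it, by log2 changes of -3.80, -3.17 and -2.97. The ATP synthase subunits atpA (-1.97) and atpD (-1.74), the haem uptake receptor gene hutA (-2.23), the glutamate synthase subunit gltD (-1.75), the flagellar rod gene flgG (-1.66) and CCNA_03157 (-3.90) were also lower. Higher in retapamulin were CCNA_00374 (3.91 ± 0.34), the cell division gene ftsE (2.67 ± 0.31), the holdfast inhibitor hfiA (2.45 ± 0.20), lovR (2.39) and zerR (2.33). The same direction held for the cell cycle regulator divK (2.17 ± 0.30), cleC (2.19), cleB (2.15) and the sigma factor gene sigU (2.13). Scaled to tRNA, cleB (0.86) and sigU (0.84) no longer passed. Changes at time 0 also fell with coding length, and the values of single genes were not adjusted for it.

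Of 26 gene lists 4 passed camera at time 0, and 1 of these, oxidative stress, also passed with an estimated correlation. For that list the estimate was 0, below the preset 0.01, so the second test was no stricter there. Among heat shock chaperones and proteases, 6 of 10 fell in retapamulin and none rose, with 6 of 10 also when adjusted over the list alone. They include dnaK (-1.45 ± 0.19), clpA (-1.02 ± 0.17), ftsH (-0.88 ± 0.16) and clpB (-0.84 ± 0.23), and camera gave an adjusted p = 0.00334 for the list (0.695 with an estimated correlation). Among oxidative stress enzymes 2 of 4 fell, the peroxidase partner ahpF (-2.45 ± 0.18) and the catalase katG (-0.84 ± 0.23), while ahpC had a log2 value of -0.49 and oxyR 0.05. The list had an adjusted p = 0.00877 (0.0221 with an estimated correlation), and did not pass with the time-0 libraries alone (0.108). Of 16 amino acid biosynthesis genes 7 fell and 2 rose, with leuC at -1.47 ± 0.21, argJ at -1.44 ± 0.24 and dapA at 1.32 ± 0.18 (0.035 under tRNA scaling, not passing). That list had an adjusted p = 0.00334 (0.695 with an estimated correlation). Of 10 toxin-antitoxin genes 9 rose, and 10 when adjusted over the list alone, among them socA (2.25 ± 0.34), higB (2.01 ± 0.30), socB (1.63 ± 0.30) and relB-3 (1.32 ± 0.27). The list had an adjusted p = 0.0229 (0.730 with an estimated correlation). The list median of 1.02 turned to -0.27 when libraries were scaled to tRNA, and 1 of the 10 genes then rose. After adjustment for coding length the median was 0.26, 3 of the 10 rose and the list did not pass (adjusted p = 0.311).

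Other groups were mixed. The median of the cold shock list went from 1.19 to 0.53 after adjustment for coding length. The cold shock genes cspB (2.37 ± 0.25), cspD (1.75 ± 0.23) and cspA (0.63 ± 0.20) rose (under tRNA scaling cspA turned to -0.66 and cspD, at 0.46, did not pass), cspC had a log2 value of -0.47, and the list did not pass (adjusted p = 0.204). In the citric acid cycle sdhC rose (1.97 ± 0.21) while sucD (-1.18 ± 0.23) and sucA (-0.73 ± 0.18) fell, and under tRNA scaling sdhC (0.68) did not pass. Of 21 cell cycle regulators 7 rose and 1 fell. rcdA (1.39), perP (1.38) and pleC (0.96) rose, though under tRNA scaling none of these passed (0.10, 0.087 and -0.33), and the master regulators ctrA and dnaA had log2 values of 0.13 and 0.22 that did not pass. recA, central to DNA repair, fell by 0.69. The values of ftsZ (-0.41), rsaA (-0.63), rne (-0.21), pilA (-0.02) and fljK (-0.22) did not pass.

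limma called 1235 of 3007 genes at time 0, 903 higher and 332 lower in retapamulin, with a median change of 0.28. The split and the sign of many genes depend on the scale: scaled to tRNA, 53 genes were higher and 1693 lower with a median of -1.01, and centred on the median gene 680 were higher and 677 lower. The median tRNA level itself was higher in the retapamulin library, at 1.14 against -0.10 and -0.20 in the chloramphenicol replicates. These levels are log2 values relative to the mean of all libraries. Retapamulin has 1 library here. Set against retapamulin at 2 minutes, the same chloramphenicol libraries gave 362 higher and 1286 lower, and cleC, divK, sigU, dapA and rcdA changed sign. There ftsE (0.75, adjusted p = 0.0531), perP (0.20, 0.544) and the oxidative stress list (0.968) did not pass.

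**Figure D2:**
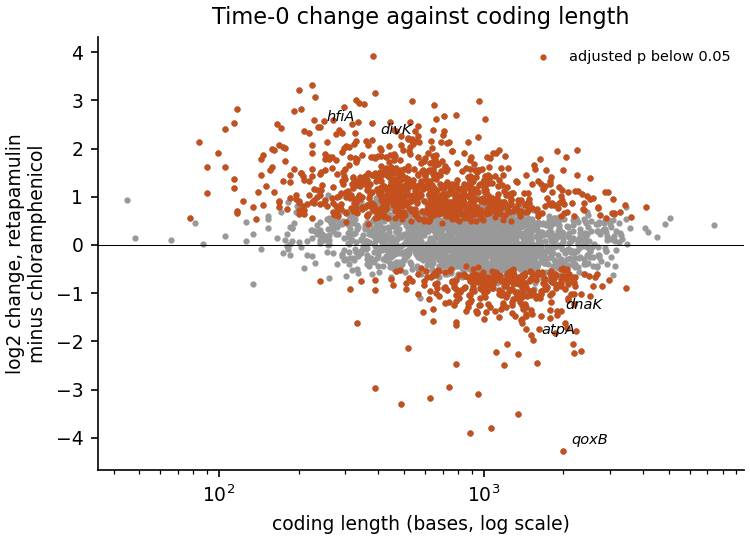
Change of each gene between retapamulin and chloramphenicol at time 0 (log2) against coding length (bases, log scale), with genes past the adjusted threshold in colour. hfiA stands at 2.45 and divK at 2.17, and the longer genes dnaK, atpA and qoxB at -1.45, -1.97 and -4.26; under tRNA scaling most called genes are lower.

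The second question is how fast mRNA was lost in each drug. Half-lives were ranked among declining genes with a symbol and a fitted level of at least 50 RPKM. In retapamulin, mRNA of the transcription elongation factor greA and the glycyl-tRNA synthetase subunit glyQ was lost fastest in this ranking. Each had a half-life of 1.11 minutes and a slope of -0.90 ± 0.06 log2 per minute (SE, n = 2 series). nuoI of respiratory complex I had a half-life of 1.27 minutes, glpX 1.29 minutes and the termination factor gene rho 1.32 minutes. The longest half-lives among declining genes were those of the surface layer protein gene rsaA at 9.04 minutes (8.12 and 10.2 in the replicates), rpsN at 7.71, btuB at 7.65, trx1 at 7.35 and stpB at 7.32. Over 0 to 4 minutes none of these 5 slopes passed, and those of trx1 (0.23) and rpsN (0.15) turned positive. The half-life of ctrA was 2.48 minutes, of dnaK 3.08, of ftsZ 4.31, of dnaA 4.73, of recA 6.08 and of rne 6.61. pilA, the pilin gene, rose on the tRNA scale with a slope of 0.11 ± 0.04 (adjusted p = 0.005). Part of this comes from scaling to tRNA, whose level changed by -0.067 and -0.063 log2 per minute in the retapamulin replicates. As deposited, pilA peaked at 35913 RPKM at 8 minutes in replicate 1 and at 32887 at 4 minutes in replicate 2. It then fell to 23493 and 20730 at 15 minutes. RPKM is a share of the library's reads, and the share in listed coding genes fell from 57.4% to 9.60% in replicate 1. The deposited values of pilA can therefore rise without more pilA mRNA.

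In retapamulin limma called 491 of 698 genes as declining and 13 as rising. The rising count was 2 on values as deposited (623 declining), 2 without retapamulin replicate 1 and 39 without replicate 2. The median slope was -0.21 log2 per minute, and the median half-life of the declining genes was 3.32 minutes (quartiles 2.19 and 4.98). These calls rest on a spread pooled with the chloramphenicol series, and they were lost when either chloramphenicol series was left out. Only abundant genes can be followed, since a gene had to exceed 25 reads at 3 times in each series. Over 0 to 4 minutes, where 2 listed times were enough, the median slope of 1794 genes was -0.35. With a value at every time the median was -0.14, and without the library of 1 minute in replicate 2 it was -0.13.

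In chloramphenicol no decline was found. Among genes with a symbol, the smallest p-values on the falling side belonged to dgcA (-0.085 ± 0.057), ftsL (-0.073 ± 0.055), gapR (-0.064 ± 0.063), hfsB (-0.063 ± 0.055) and doc (-0.060 ± 0.060). On the rising side, again among genes with a symbol, they belonged to flgB (0.130 ± 0.055), btuB (0.098 ± 0.054), rsaA (0.091 ± 0.045), pilA (0.083 ± 0.036) and rpmD (0.080 ± 0.044). limma called 0 of 2777 genes in either direction, with 2 falling and 18 rising at an unadjusted p below 0.05. A single fit of all libraries called 1 gene as declining, and with the repeated library placed at 0 or 2 minutes 56 and 53 of 3000 genes passed as rising. The median slope was 0.029 log2 per minute on the tRNA scale (0.060 in replicate 1 and -0.0040 in replicate 2) and -0.035 on the values as deposited, where 0 genes passed and 988 had an unadjusted p below 0.05. On centred slopes 3 of 26 lists passed camera, ribosomal proteins (adjusted p = 5.47e-07), flagellins (0.00269) and toxin-antitoxin genes (0.0470), and none did with an estimated correlation (0.358, 0.358 and 0.119).

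**Figure D3:**
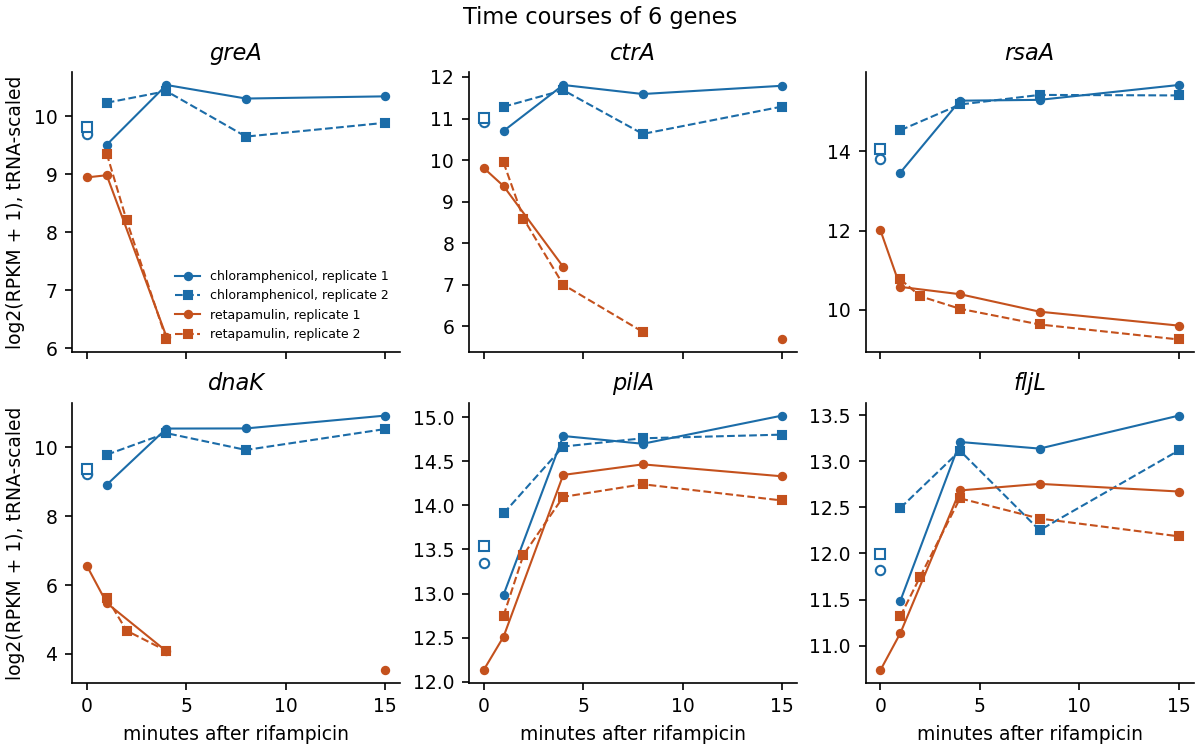
Level of 6 genes (log2(RPKM + 1), scaled to tRNA) against minutes after rifampicin, with 1 line per replicate and drug. Open symbols are the repeated chloramphenicol library, drawn at 0, and missing points are blanks. greA has a half-life of 1.11 minutes in retapamulin and rsaA of 9.04 minutes, while pilA has a slope of 0.11.

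The difference in slope was tested directly. mRNA of glyQ was lost faster in retapamulin by -0.93 ± 0.09 log2 per minute (SE, n = 2 series per drug), and greA by -0.90 ± 0.09. The other genes with the most negative differences were rho (-0.82), nuoI (-0.81), glpX (-0.77), the surface layer export gene rsaE (-0.77), ctaG (-0.74), the ribosomal protein gene rpsU (-0.74), metZ (-0.73), clpA (-0.73) and CCNA_01621 (-0.92). Here too the slopes of single genes rest on unlike windows of time. The differences of ctrA (-0.42), dnaK (-0.40), ftsZ (-0.27), dnaA (-0.25), recA (-0.22), rsaA (-0.20) and rne (-0.20) passed, and those of fljK (-0.18) and pilA (0.023) did not. Among ribosomal proteins 20 of 26 genes were lost faster, among complex I genes 13 of 14, and among RNA polymerase and elongation factor genes 6 of 6. Over all tested genes it was 479 of 697. None of these lists passed camera (adjusted p = 0.736, 0.295 and 0.0829).

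limma called 479 of 697 genes, all lower in retapamulin and none higher, with 656 of the 697 differences negative. Without retapamulin replicate 2, 22 were higher and 353 lower. Without either chloramphenicol series 0 genes passed, with 148 and 222 at an unadjusted p below 0.05.

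**Figure D4:**
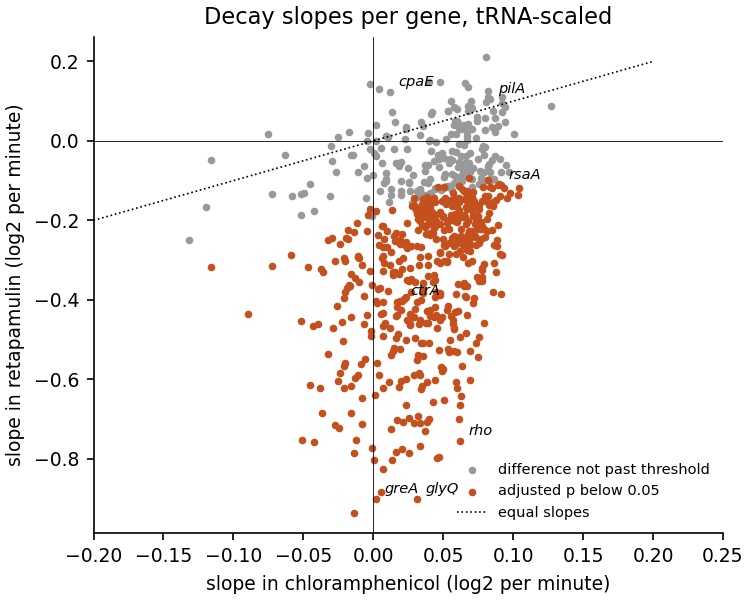
Slope in retapamulin against slope in chloramphenicol for each gene (both log2 per minute, scaled to tRNA), with genes whose difference passed the threshold in colour and a dotted line of equal slopes. Called genes lie below the line, glyQ at -0.90 and rho at -0.76 in retapamulin.

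Slopes were then compared after subtracting the median of each series. Relative to the median gene, the pilus genes cpaE (0.35 ± 0.03) and pilA (0.27 ± 0.01) had higher slopes in retapamulin than in chloramphenicol, as did the flagellin gene fljL (0.26 ± 0.01). The same held for rtrA (0.28), ftsI (0.27), mutS (0.26), cdzD (0.24) and cdzC (0.23) of the contact-dependent bacteriocin, hutA (0.23), the efflux gene acrB4 (0.23) and CCNA_00243 (0.39). Of 26 ribosomal protein genes 8 were higher, among them the neighbours rpmD (0.19), rpsE (0.18) and rplR (0.17), and 10 were lower. Lower were glyQ (-0.69 ± 0.12), greA (-0.66 ± 0.09), CCNA_01621 (-0.68), rho (-0.57), nuoI (-0.57), rsaE (-0.52), rpsU (-0.49), metZ (-0.48), clpA (-0.48), bamF (-0.48) and nuoE (-0.46). Of 14 complex I genes 4 were lower, with nuoK at -0.41 and nuoJ at -0.28.

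limma called 165 genes higher and 129 lower in this relative comparison, and 87 higher and 8 lower when libraries were scaled to summed tRNA. The calls and SEs rest on a spread pooled over both drugs, which was assumed to be alike in both. Without either chloramphenicol series 59 and 58 genes passed, and without retapamulin replicate 1 or 2 the counts were 690 and 917. Of 18 gene lists none passed camera on the slope difference as fitted, with 3 at an unadjusted p below 0.05. On the centred slope difference 1 list passed, the swarmer cell markers (median 0.088, adjusted p = 0.0147, and 0.0109 with an estimated correlation). The estimated correlation was 0 for this list, so that second test was no stricter. Of its 6 members 2 rose relative to the median gene, 1 fell (cheYI, -0.084 ± 0.017) and podJ had a value of 0.11. cheYI did not pass over 0 to 8 minutes (0.14) or 0 to 4 minutes (0.18). The list did not pass in 10 of 21 alternatives, and without retapamulin replicate 2 its median was -0.014.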

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

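The tests of random length bias, of the length trend at time 0, of separate preparation of the drugs' libraries and of the tRNA level were chosen after the results they address were seen, as was the demand that a value lie 2 standard errors beyond its limit to decide a test. The slope differences of 479 genes between the drugs, and of 294 genes relative to the median gene, stand out because the drugs differed in a direct test.

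Values in retapamulin relative to chloramphenicol fell with coding length, with rank correlations across genes of -0.323 and -0.346 at time 0 and -0.490 to -0.550 at 1 minute (genes are not independent replicates). A length bias that varies at random between libraries is argued against: the largest correlation between replicates of 1 drug and time was 0.182 ± 0.056 (SE). The length trend as the whole source of the gene list results at time 0 is also argued against, since 3 of the 4 lists still passed after adjustment for length, although with an estimated correlation only oxidative stress did (adjusted p = 0.0335, against 0.920 for the others), and the toxin-antitoxin median went from 1.02 (SD 0.51 over genes) to 0.26 (SD 0.61). Separate preparation of the drugs' libraries cannot be told apart from the drug itself, since the median correlation of -0.498 is all between drugs and the labels give no batch. The trend nearest 0 at time 0 was -0.323 ± 0.023 (SE). The retapamulin library there preceded rifampicin, so this value could not come from loss after rifampicin in retapamulin. It says nothing about faster loss of long mRNAs in retapamulin before rifampicin, which was not tested. For later times, faster loss of long mRNAs after rifampicin in retapamulin stays open. The correlation of relative slope with length was -0.0969 ± 0.038 (SE), too close to the limit of -0.1 set for it.

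The tRNA level as deposited fell over the time course although tRNA was meant as a stable control. In chloramphenicol, growth of reads outside coding genes is argued against as the source, since their share grew by at most 1.05 times from 1 to 15 minutes over listed genes, or 1.07 times with blanks at 25 reads. In retapamulin that share grew by at least 1.58 times over listed genes, or 1.42 times with blanks at 25 reads. Dilution of tRNA by other reads outside coding genes stays open. The growth is no evidence for it, since loss of coding reads alone also raises that share. No biological explanation was tested. Slopes scaled to tRNA may therefore be too high in both drugs, and relative slopes may be affected too, since their calls went from 294 to 95 with summed tRNA.

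The genes with the most negative relative slopes in retapamulin were mostly listed at few times: 108 of 129 had 6 values over both series, against a median of 10 for the 165 genes on the other side. Slopes taken over shorter windows may account for part of this, since loss was steeper early. Over 0 to 4 minutes the median relative difference of the 129 genes was -0.205 ± 0.021 (SE). This decides nothing, because the genes were picked for negative slopes that rest largely on the same early values, so a real difference in decay between the drugs stays open for these genes too.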

How the results depend on the processing

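The alternatives that place the repeated library, compare 1 or 2 minutes in place of time 0, need a value at every time, use the Tobit fit, leave out a single doubted library, centre the slopes for the lists or adjust for coding length were chosen after seeing the data. Whether libraries with the same replicate number belong together could not be told. Between the drugs, deviations of same-numbered libraries had a median correlation of 0.012 (-0.164 to 0.160). Within a drug, where they were treated as 1 series, the median was 0.052 in chloramphenicol and -0.046 (-0.446 to 0.274) in retapamulin. The check therefore shows neither that the numbers are unrelated nor that they mark a series. With the replicate block 1130 genes passed at time 0, 182 relative slope differences (77 higher, 105 lower), 1 decline in chloramphenicol with 27 rises among 697 genes, and 1 list on slopes. Leaving out retapamulin replicate 1 or 2 at time 0 gave no value, since the first is the only library and the other is blank. Depth limits which genes have slopes, since a gene drops out at 25 reads. The cause of the changes below was not tested, except where fewer genes or libraries entered.

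At time 0 the count of 1235 genes became 818 at 50 RPKM (fewer genes tested, 1805), 1908 with the time-0 libraries alone and 463 of 686 at 1 minute; without chloramphenicol replicate 1 or 2 it was 890 and 837. The 4 lists became 1 at 1 minute and 7 at 2 minutes, 3 with the time-0 libraries alone, where oxidative stress (adjusted p = 0.108) no longer passed, and 3 after adjustment for length, where the toxin-antitoxin list no longer passed. The direction of the split turned with tRNA scaling (53 higher, 1693 lower) and at 2 minutes (362 higher, 1286 lower). Scaling to tRNA turned oxyR (-1.24), cspA (-0.66), pleC (-0.33), ctrA (-1.16), dnaA (-1.07) and the toxin-antitoxin median (-0.27). Centring turned oxyR (-0.23), ctrA (-0.15) and dnaA (-0.061). Without chloramphenicol replicate 1 or 2 oxyR was -0.062 and 0.16, and pilA -0.067 and 0.030. At 1 minute cspC was 0.038 and pilA 0.66. At 2 minutes cleC (-0.999), divK (-0.39), sigU (-0.11), ahpC (0.096), oxyR (-0.72), dapA (-0.45), rcdA (-1.08), ctrA (-1.31), dnaA (-1.65) and pilA (1.07) changed sign, and ftsE (0.75), perP (0.20) and the oxidative stress list (adjusted p = 0.968) did not pass. The amino acid list did not pass at 1 minute (adjusted p = 0.166). Without chloramphenicol replicate 2 clpB, katG, cspA and recA did not pass, nor did recA without replicate 1.

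In retapamulin the 491 declines became 279 over 1 to 15 minutes, 139 of 227 genes with a value at every time, 1410 of 1796 with the Tobit fit and 226 of 423 without the library of 1 minute in replicate 2; leaving out a series gave 0 to 465. The 13 rises became 2 on values as deposited, 6 over 1 to 15 minutes, 28 in a single fit, and 2 and 39 without retapamulin replicate 1 or 2. The Tobit fit and the 0 to 4 minute window needed only 2 listed times, fewer than the main fit, so more genes entered. What the Tobit fit alone did to the declines or the median slope therefore cannot be told. The median slope of -0.21 became -0.30 over 0 to 8 minutes, -0.35 over 0 to 4 minutes and -0.30 with the Tobit fit. It was shallower over 1 to 15 minutes (-0.15), with a value at every time (-0.14) and without the library of 1 minute in replicate 2 (-0.13, a half-life of 7.89 minutes in place of 4.75). Without retapamulin replicate 1 or 2 it was -0.27 and -0.15. Over 0 to 4 minutes trx1 (0.23) and rpsN (0.15) changed sign. In chloramphenicol a single fit of all libraries, the block and the repeated library at 2 minutes each gave 1 decline in place of 0, and placing it at 0 or 2 minutes gave 56 and 53 rises. The median slope was -0.035 on values as deposited, 0.25 over 0 to 4 minutes, and -0.0035 and 0.061 without chloramphenicol replicate 1 or 2. Over 0 to 4 minutes dgcA (0.017), ftsL (0.056), hfsB (0.083) and gapR (0.014) changed sign, and flgB did in the Tobit fit (-0.00103).

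The 479 slope differences became 796 over 0 to 4 minutes (1775 genes), 284 over 1 to 15 minutes, 141 with a value at every time, 1272 of 1778 with the Tobit fit, 233 without the library of retapamulin at 1 minute in replicate 2 and 481 without that of chloramphenicol at 8 minutes in replicate 2; leaving out a series gave 0 to 468. In place of 0 higher genes there were 22 without retapamulin replicate 2, 1 without replicate 1, 3 with summed tRNA, 3 with the block, 2 on values as deposited and 1 over 0 to 4 minutes. pilA was between -0.012 and 0.057 when a series was left out, with -0.0082 without chloramphenicol replicate 2. The 294 relative differences became 95 with summed tRNA, 193 in a single fit, 166 with a value at every time and 192 without retapamulin at 1 minute in replicate 2; leaving out a series gave 58 to 917. Here too the 0 to 4 minute window and the Tobit fit needed 2 listed times in place of 3. Chloramphenicol slopes over 0 to 4 minutes rest on 1 and 4 minutes alone, since the repeated library was left out. cheYI was 0.14 over 0 to 8 minutes and 0.18 over 0 to 4 minutes. The count of 0 lists became 1 at pseudocount 10, 4 over 0 to 4 minutes, 1 over 1 to 15 minutes, 2 in a single fit, 1 without either chloramphenicol series, 1 with a value at every time, 1 with the Tobit fit, 1 without retapamulin at 1 minute in replicate 2 and 1 on centred slopes. The swarmer list median was -0.014 without retapamulin replicate 2. That list also did not pass at 50 RPKM, on values as deposited, with summed tRNA, over 0 to 8 or 1 to 15 minutes, in a single fit, without retapamulin replicate 1, with a value at every time or without retapamulin at 1 minute in replicate 2. With summed tRNA the tRNA slopes in retapamulin were -0.071 and -0.034.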

Other observations

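The gene choices in this part were made after the values were seen. At 15 minutes in retapamulin 10 genes held 47.1% and 49.0% of the reads in listed coding genes in the replicates. The same genes held 8.53% at time 0. In chloramphenicol at 15 minutes they held 13.9% and 14.5%. Reads in blank genes are not counted, so the shares in this paragraph are upper limits. In retapamulin at 15 minutes listed coding genes held 9.60% and 7.42% of the library. With every blank gene at its limit, coding genes would hold 16.2% and 16.9%. The retapamulin shares at 15 minutes could therefore be well below those given. The largest shares belonged to CCNA_00530, with 8.74% and 8.75%, and CCNA_00035, with 6.58% and 6.63%. The flagellin gene fljL held 6.13% and 6.04%, and the pilin gene pilA 3.65% and 4.16%, up from 0.516% and 0.256% at time 0. The surface layer gene rsaA went the other way, from 4.80% to 2.82% and 3.05%, and held 9.99% and 10.5% in chloramphenicol.

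The level of pilA in retapamulin replicate 1 went from 9873 RPKM at time 0 to 29081 at 4 minutes and 23493 at 15 minutes, and in replicate 2 from 15479 at 1 minute to 32887 at 4 minutes and 20730 at 15 minutes. cdzC, a gene of the contact-dependent bacteriocin, went from 5170 RPKM at time 0 to 11894 at 4 minutes and 7027 at 15 minutes in replicate 1, and from 6702 at 1 minute to 12877 at 4 minutes and 5393 at 15 minutes in replicate 2. Its slope in retapamulin did not pass (0.049, adjusted p = 0.299). In chloramphenicol replicate 1 pilA had 9477 RPKM at 1 minute and 12187 at 15 minutes. RPKM is a share of the library's reads, so the rises in retapamulin do not show that the amount of these mRNAs grew.

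Among other terminal oxidase genes coxC fell in retapamulin at time 0 (-1.21, adjusted p = 0.0421). At 1 minute coxC had 200 and 608 RPKM in the retapamulin replicates, against 508 and 507 in chloramphenicol. The log2 changes of cydA (-0.43), cydB (0.015), coxA (-0.69), coxB (-0.32) and coxE (0.52) did not pass, and the cco genes were too low to be tested.

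The library of chloramphenicol at 8 minutes in replicate 2 stood apart from its neighbours in time. Its gene values had an SD of 0.37 log2 around the mean of 4 and 15 minutes, against 0.19 in replicate 1.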
